A study of Homo sapiens with 12 samples.

How the data were processed

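RNA from 12 cultures of 2 human breast cancer lines, SUM-159-2 and MDA-MB-231-2 in the labels, was analysed, with 3 libraries in each of 4 groups: SUM-159 without and with the label Doxy, and MDA-MB-231 without and with it. Per the labels' protocols, MDA-MB-231 was grown in DMEM with serum, and SUM-159 in F12 with less serum, insulin and hydrocortisone. Per the series design text, total RNA was poly-A selected and sequenced on a HiSeq 2500 with 3 biological replicates of each kind. The columns of the table were matched to the samples by the descriptions in the labels, which write the middle of the name in a slightly different way, and the letter and number in the name decided each match.

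The authors aligned reads with Bowtie2 (version 2.1.0) to the human genome hg38 and quantified genes with RSEM (version 1.2.15), per the submitters' processing notes. The deposited table holds expected counts per gene symbol, not normalized, for 26475 symbols. Of its values 9.65% were not whole numbers, as arises when RSEM divides reads that fit several genes or transcripts. The gene annotation, the strand setting and any filter used by the submitters were not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies cannot be assigned with certainty. The mitochondrially encoded genes have no entry in the table, which left 35 of the 36 lists of genes testable.

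Expected counts were rounded and tested in R (version 4.3.3) with edgeR (version 4.0.16). Genes were kept by filterByExpr with a minimum count of 10 and a minimum total count of 15, which left 15299. Libraries were scaled by TMM factors, and the 4 groups were fitted together by the quasi-likelihood method with group as the only term. Adjusted p-values are Benjamini-Hochberg values over all genes kept, with a threshold of 0.05. Counts scaled to 1e6 per library (CPM) were computed from the deposited counts over the library totals adjusted by TMM factors, and levels are given as mean ± SD. A standard error is the log2 fold change over the normal quantile of its quasi-likelihood p. The common biological coefficient of variation was 9.11%. Coordinates are from GENCODE 29 (GRCh38), which held 23926 of the 26475 symbols (90.4%).

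The comparisons were Doxy against no Doxy in each line, the difference of these effects, the lines without Doxy, and the overlap of the Doxy calls of both lines with the overlap of independent lists. The Doxy effects of the lines share no library. The gene lists cover MYC and its targets, growth and metabolism, cell cycle, stress and signalling, and markers of other cell types, and were written by hand before the data were examined, as were the tests, the alternatives and the rule for naming genes. Lists were tested with camera from limma (version 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 35 lists of a comparison. Camera with an estimated correlation and fry were alternatives. The p with an estimated correlation stands beside the calls that it ends. A count "adjusted over the list alone" adjusts the p-values of the list's genes among themselves.

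Genes were named by a fixed rule: members of the MYC network that pass in either line, the 8 largest rises and the 8 largest falls of a Doxy effect, up to 4 members with the lowest p of each described list and those that go against it, the 6 genes with the lowest p in each direction of the difference between the lines, and the 6 largest differences between the lines in each direction with the cell type markers that pass. The rule by size asked for an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap between the 3 and 3 libraries, which chance gives in 10% of genes. Some genes that meet these rules are not reported here.

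The libraries held from 18979369 to 25836318 expected counts. The 10 most abundant genes took 4.82% to 8.48% of them and ribosomal RNA genes 0.904% to 1.63%. That second share went with Doxy without overlap in both lines. It was 1.185% to 1.354% without Doxy and 1.439% to 1.631% with it in SUM-159. In MDA-MB-231 it was 0.9039% to 1.167% and 1.34% to 1.436%. A difference in RNA quality or poly-A selection that goes with Doxy therefore cannot be told apart from its effect. A gene without counts allows up to 3 counts, 0.11 to 0.16 CPM, and 5455 genes had none in any library. Intervals and floors cover counting error only. No library was a copy of another: the chi-square per gene between pairs ran from 2.26 to 30.6. Pearson correlations of log2 CPM across genes were 0.986 to 0.992 within a group, 0.973 to 0.988 between the groups of a line and 0.792 to 0.817 between lines, and the first principal component, with 87.3% of the variance, separated the lines. The labels give no batch, day or lane.

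The procedure was tested on simulated counts with 200 changed genes per comparison. At changes of 1.25, 1.5, 2 and 4-fold it recovered 20.0%, 74.0%, 96.0% and 98.0% in SUM-159 (15090 genes), 16.0%, 70.0%, 94.0% and 96.0% in MDA-MB-231 (15082 genes), 8.0%, 48.0%, 76.0% and 94.0% for the difference of the effects (15116 genes) and 16.0%, 82.0%, 82.0% and 100.0% between the lines (14064 genes). Of the calls, 3.36%, 8.0%, 1.74% and 8.5% were of unchanged genes. With the mitosis list lowered in simulated SUM-159 Doxy libraries, 1 of 35 lists was called, the mitosis list. The simulated genes varied independently, while the mitosis list had an estimated correlation of 0.157 in the data. This simulation therefore cannot show how often camera calls unchanged lists whose genes vary together.

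The alternatives fixed beforehand were DESeq2 (version 1.42.0), limma-voom, relative log expression, upper-quartile and library-total scaling, no filter and a filter at 1 CPM in 3 libraries, counts not rounded, only the 6 libraries of a line, the replicate number as a block, and each library left out in turn. Alternatives chosen after the data were examined were the 8 libraries with few lymphocyte transcripts, a term for the other 4 libraries, the removal of genes at least 8 times higher in MDA-MB-231, the subtraction of an MDA-MB-231 share from SUM-159 Doxy replicates 2 and 3, and the removal of each library's trend on GC content (a smooth curve with a span of 0.3). The 4 libraries set apart were those with a lymphocyte sum more than 3 times that of the lowest library. The 29 MDA-MB-231 markers were genes with a mean over 50 CPM in both MDA-MB-231 groups and under 0.5 CPM in SUM-159 without Doxy. These thresholds and 5 further gene lists were also chosen after the data were examined. All sample columns of the deposited table were used.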

Results

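Gene expression was measured by RNA sequencing of poly-A selected RNA in cells labelled SUM-159-2 and MDA-MB-231-2. They are called SUM-159 and MDA-MB-231 here, after the established human lines of triple-negative breast cancer whose names they carry, and how they were derived was not given in the sources used here. Each line gave 3 libraries labelled Doxy and 3 without that label, 12 in all, and the series design text calls the samples of each kind biological replicates. The series title speaks of an inducible knockdown of c-MYC, so the question taken from it was what changes in each line when MYC is lowered. The labels do not spell out Doxy, and its dose and duration were not given in the sources used here. No library of cells without the construct was analysed here, so an effect of Doxy itself is not separated from that of MYC. The summed expected counts ran from 22388595 to 24646163 per library in SUM-159 without Doxy, from 19920537 to 24956644 in SUM-159 Doxy, from 21565385 to 23279073 in MDA-MB-231 without Doxy and from 18979369 to 25836318 in MDA-MB-231 Doxy. Of 26475 genes, 15299 passed the expression filter.

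MYC, the transcription factor named in the title, was lower in every library labelled Doxy than in every library of the same line without it. In SUM-159 the expected counts of MYC were 16464, 15519 and 15497 without Doxy and 11177, 10373 and 9355 with it. In MDA-MB-231 they were 6977, 5688 and 6519 without Doxy and 2652, 2897 and 2355 with it. In CPM, counts scaled to 1e6 per library with TMM factors, MYC went from 689 ± 33.2 to 495 ± 24.2 CPM in SUM-159, a fold of 1.39, and from 278 ± 24.3 to 114 ± 7.13 CPM in MDA-MB-231, a fold of 2.43 (SD, n = 3). The log2 fold changes were -0.48 (SE 0.11, adjusted p = 0.000428) and -1.28 (SE 0.20, adjusted p = 3.41e-08) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The direction goes with the title and against the genotype label, which gives the libraries labelled Doxy as expressing c-MYC and the others as not expressing it. Groups are therefore named by the Doxy label alone, and every direction below rests on that label. MYC lies on chromosome 8 at 127735434 to 127741434, plus strand, in GENCODE 29 (GRCh38).

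**Figure D1:**
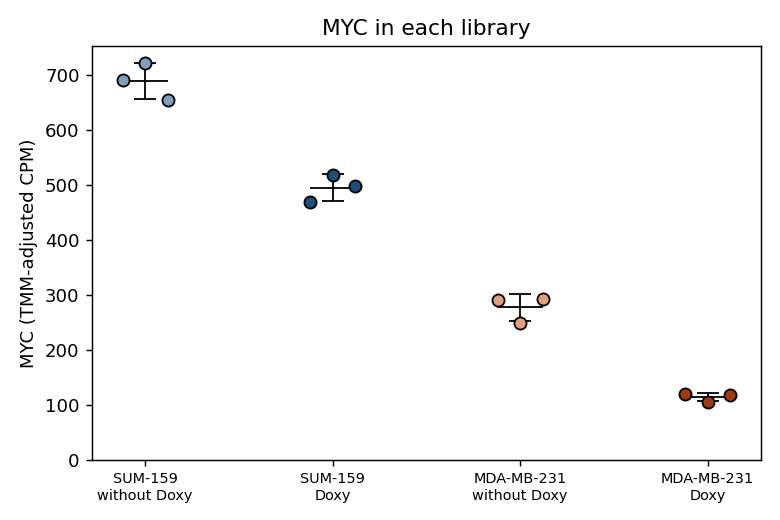
MYC in each of the 12 libraries (y axis, TMM-adjusted CPM, linear from 0) by group (x axis). Points are libraries, horizontal bars the group mean and error bars 1 SD (n = 3): the Doxy libraries lie between 470 and 518 in SUM-159 and between 106 and 119 in MDA-MB-231, below the libraries without Doxy.

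RNAs of some proteins that share the MYC partner MAX changed as well. In MDA-MB-231, 8 of 12 measured members of the MYC network fell and 2 rose (8 and 2 when adjusted over the list alone). MYC itself is among the lower ones, in the count and in the test of the list. MXI1 (log2 fold change -0.90, SE 0.15) and MXD1 (-1.10, SE 0.19), both antagonists of MYC, fell, as did MAX itself (-0.44, SE 0.11), whereas the antagonist MXD4 rose (0.74, SE 0.18), and so did MXD3 (1.11, SE 0.27), whose reads RSEM divides with similar sequences. In SUM-159, 5 of 12, MYC included, fell and 1 rose (5 and 1 when adjusted over the list alone), with MXI1 lower (-0.30, SE 0.08) and MXD4 higher (0.58, SE 0.16). In the 8 libraries with few lymphocyte transcripts, described with the SUM-159 totals, which leave 1 SUM-159 Doxy library, those 2 genes had log2 fold changes of -0.24 (adjusted p = 0.092) and 0.44 (0.0559). The list was called by camera in MDA-MB-231 (adjusted p = 0.0358, and adjusted p = 0.28 with an estimated correlation) but not in SUM-159 (adjusted p = 0.0865). The MDA-MB-231 call ended without replicate 3 of the group without Doxy (adjusted p = 0.0531) and without Doxy replicate 2 (adjusted p = 0.0536), and with the trend on GC content removed (adjusted p = 0.0721).

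In SUM-159, genes of DNA replication and growth were lower with Doxy. Of 52 measured DNA replication and S phase genes, 50 fell and none rose, with a median log2 fold change of -0.71 (50 fell when adjusted over the list alone). E2F1, a transcription factor that drives entry into S phase, went from 32.6 ± 2.16 to 13.2 ± 1.64 CPM (SD, n = 3), 2.47-fold lower (adjusted p = 3.05e-06). The replicative helicase subunits MCM4 (2.07-fold) and MCM3 (1.8-fold) fell too, as did the sliding clamp PCNA (1.68-fold), whose reads can be shared with pseudogenes. Of 66 direct MYC targets, 51 fell and 2 rose (54 and 3 when adjusted over the list alone), with a median of -0.48. They included the uracil-DNA glycosylase UNG (2.3-fold lower), the nucleolar protein NOLC1 (1.61-fold) and the pseudouridine synthase DKC1 (1.55-fold). Of 75 ribosome biogenesis factors, 53 fell and none rose (55 fell when adjusted over the list alone), RRP12 among them (1.73-fold lower). Of 34 enzymes of nucleotide synthesis, 19 fell and 1 rose (20 and 2 when adjusted over the list alone), and the purine enzymes PAICS (1.58-fold lower), ATIC (1.44-fold) and GART (1.42-fold) had the lowest p. Chaperones of the endoplasmic reticulum fell in 12 of 23 cases and rose in 1 (the same counts when adjusted over the list alone), among them HYOU1 (1.5-fold lower) and HSPA5 (1.38-fold). Camera's adjusted p was 2.51e-35 for replication, 5.8e-26 for MYC targets and 4.26e-24 for ribosome biogenesis. It was 1.66e-08 for nucleotide synthesis and 1.04e-05 for the chaperones, and all 5 lists were also called with an estimated correlation. Some members are shared, so these calls are not independent. MCM4 is both a MYC target and a replication gene, and NOLC1 and DKC1 are both MYC targets and ribosome biogenesis factors. The cytosolic ribosomal proteins had 4 of 78 members lower and none higher (1 lower when adjusted over the list alone), a median of -0.02 and no call (adjusted p = 0.0837).

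Mesenchymal, matrix and cell cycle inhibitor genes were higher with Doxy in SUM-159. Of 37 genes of epithelial-mesenchymal transition, 26 rose and none fell, with a median of 0.50 (28 rose when adjusted over the list alone). CTGF, a matricellular growth factor, went from 6.87 ± 0.541 to 25.5 ± 2.28 CPM (SD, n = 3), 3.7-fold higher (adjusted p = 9.46e-08), the myosin light chain MYL9 was 2.35-fold higher and fibrillin FBN1 1.95-fold. Of 21 YAP and TEAD targets, 14 rose and none fell (the same when adjusted over the list alone), among them NT5E, the ecto-enzyme CD73 (2.67-fold), IGFBP3 (1.87-fold) and the receptor kinase AXL (1.52-fold). Of 41 collagen and matrix genes, 25 rose and 2 fell (28 and 3 when adjusted over the list alone), with thrombospondin THBS1 1.77-fold, COL8A1 1.53-fold and fibronectin FN1 1.38-fold higher. Of 24 CDK inhibitors and genes repressed by MYC, 13 rose and 2 fell (14 and 2 when adjusted over the list alone), with CDKN1C at 3.03-fold, CDKN2D at 1.87-fold and CDKN2C at 1.62-fold. Camera's adjusted p was 1.73e-10 for the mesenchymal list, 2.89e-07 for YAP and TEAD targets, 2.89e-07 for matrix and 0.00285 for the inhibitors. The matrix list had adjusted p = 0.0542 with an estimated correlation, and the other 3 were called with it. These lists share members too: CTGF is on the mesenchymal and the YAP and TEAD lists, and FBN1 on the mesenchymal and matrix lists. THBS1 is on the matrix list and on that of inhibitors and genes repressed by MYC.

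Interferon, lysosomal and basal genes also rose in SUM-159. Of 51 interferon-response genes, 21 rose and 2 fell (22 and 3 when adjusted over the list alone). IFI6 (2.02-fold), IRF9 (1.71-fold) and STAT2 (1.5-fold) rose, the last 2 being partners in the interferon-activated transcription factor. IRF1 fell (-0.43, SE 0.13). Of 48 lysosome and autophagy genes, 21 rose and 1 fell (24 and 2 when adjusted over the list alone), among them the sphingomyelinase SMPD1 (1.96-fold) and the cathepsin CTSB (1.51-fold). Of 13 basal and myoepithelial markers, 7 rose and none fell (9 rose when adjusted over the list alone), with the myosin kinase MYLK at 1.58-fold and MME at 1.41-fold. These 3 lists were called at adjusted p = 1.78e-05, 0.000139 and 0.00634, and had adjusted p = 0.0937, 0.16 and 0.0591 with an estimated correlation. Histone transcripts HIST1H1C (2.41-fold), HIST2H2BE (2.32-fold) and HIST1H2BK (1.62-fold) were among 5 of 14 RNAs of mostly non-polyadenylated classes that rose, none of which fell (the same when adjusted over the list alone; adjusted p = 0.0156, and adjusted p = 0.258 with an estimated correlation). That call ended without replicate 1 of the group without Doxy (adjusted p = 0.0521). It also ended with the trend on GC content removed (adjusted p = 0.0532). Ribosomal RNA genes likewise took a larger share of the SUM-159 Doxy libraries, 1.439% to 1.631% against 1.185% to 1.354% without Doxy. Whether RNA quality or poly-A selection differed between the groups was not tested.

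Smaller shifts in SUM-159 touched amino acid metabolism and mitochondrial translation. Of 21 serine and one-carbon genes, 8 fell and 2 rose (9 and 4 when adjusted over the list alone), with the folate enzyme MTHFD1L 1.61-fold lower. Of 36 targets of ATF4, the transcription factor of the integrated stress response, 12 fell and 2 rose (14 and 3 when adjusted over the list alone): TRIB3 (-0.55, SE 0.13) and PSAT1 (-0.35, SE 0.08) fell, and VLDLR (0.83, SE 0.18) and CBS (0.46, SE 0.14) rose. Of 80 mitochondrial ribosomal proteins, 15 fell and 2 rose (the same when adjusted over the list alone), with MRPL15 at -0.40, SE 0.10. Of 25 heat shock proteins, 6 fell and 3 rose (9 and 3 when adjusted over the list alone), the mitochondrial chaperonin HSPD1 among the lower ones (-0.58, SE 0.12). Of 52 mitotic genes, 4 fell and 3 rose (3 and 3 when adjusted over the list alone), and the kinesin KIF20A was one that rose (0.41, SE 0.10). Median log2 fold changes were -0.15 for serine, -0.12 for ATF4 and -0.05 for mitochondrial ribosomal proteins. They were -0.09 for heat shock and -0.10 for mitosis. Camera compares a list with all other genes, so its calls are relative to them. Camera called these 5 lists as lower at adjusted p = 0.012 for serine, 0.0107 for ATF4, 0.0104 for mitochondrial ribosomal proteins, 0.0344 for heat shock and 0.0416 for mitosis, and they had adjusted p = 0.0542, 0.316, 0.427, 0.258 and 0.549 with an estimated correlation. Of these calls, mitochondrial ribosomal proteins ended without replicate 2 of the group without Doxy (adjusted p = 0.0516), heat shock without replicate 3 of that group (0.0531) or Doxy replicate 2 (0.0589), and mitosis without replicate 3 of that group (0.133), Doxy replicate 2 (0.0913) or Doxy replicate 3 (0.0593), and with the trend on GC content removed (0.0796). With fry mitochondrial ribosomal proteins (adjusted p = 0.114) and mitosis (0.262) were not called. The p53 targets (8 of 30 higher, 4 lower, the same when adjusted over the list alone) and glycolytic genes (9 of 24 higher, 4 lower, likewise) were not called (adjusted p = 0.565 and 0.361).

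Among the largest rises of single genes in SUM-159 under the naming rule was that of DKK1, a secreted Wnt antagonist. DKK1 went from 3.04 ± 0.456 to 15.8 ± 1.96 CPM (SD, n = 3). Others were of TP53INP1, a p53 target (5.39-fold), of OLFML3 (4.41-fold), of the calcification inhibitor MGP (3.96-fold) and of the carboxypeptidase CPA4 (3.93-fold). PSG1 also rose (5.44-fold), with reads that RSEM divides among similar genes of its family. The largest falls were of FAM111B (2.5-fold), E2F1, LAMP3 (2.45-fold), INHBE (2.45-fold), WNT10B (2.4-fold), UNG, the recombination factor XRCC2 (2.23-fold) and the replication factor MCM10 (2.19-fold). IGFBP5 went from 2.84 ± 0.665 to 35.3 ± 27.4 CPM (SD, n = 3), and its call ended without replicate 1 of the group without Doxy (adjusted p = 0.0592) or Doxy replicate 3 (adjusted p = 0.0519). In all, 4105 of 15299 genes changed with Doxy in SUM-159, 2496 higher and 1609 lower, and 502 of them at least 2-fold, 438 higher and 64 lower (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The split of higher and lower calls depended on the libraries scaled together: with the 6 SUM-159 libraries alone it was 2056 against 2108. The split of changes of at least 2-fold was not recounted in other settings. Whether RNA of MDA-MB-231 or of lymphocytes in Doxy replicates 2 and 3, described next, adds to those rises was not tested. Without replicate 1 of the group without Doxy the count was 2719, without Doxy replicate 2 it was 2658 and without Doxy replicate 3 it was 2691.

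SUM-159 Doxy replicates 2 and 3 held more lymphocyte transcripts and more RNA of MDA-MB-231 marker genes than the other SUM-159 libraries. Summed over PTPRC, CD3D, CD3E, CD3G and CD2, lymphocyte transcripts reached 8.97 and 8.08 CPM there, against 1.96 to 2.76 CPM in the other 4 SUM-159 libraries, and 29 marker genes of MDA-MB-231 stood at 1.22% and 1.26% of their MDA-MB-231 level against 0.215% to 0.311%. Leukocyte markers (4 of 11 higher) and luminal epithelial markers (7 of 16 higher, 2 lower) moved with those 2 libraries. So did genes of the NF-kB and cytokine list (8 of 34 higher, 2 lower) and CD74 (4.53-fold higher). None of the 3 lists was called by camera (adjusted p = 0.0557, 0.0865 and 0.312). With an MDA-MB-231 share subtracted from those 2 libraries, CD74 stayed higher by edgeR (log2 fold change 1.35, adjusted p = 0.00353). IGFBP5 did too (3.62, adjusted p = 0.0133). The subtraction takes away no lymphocyte RNA, so these calls do not show a rise free of foreign RNA. CD74 stood at 6.68 and 7.68 CPM in those 2 libraries. It was 1.68 CPM in Doxy replicate 1 and 1.01 to 1.26 CPM without Doxy. In the 8 libraries with few lymphocyte transcripts, which leave 1 SUM-159 Doxy library, the lists had 1, 1 and 0 members higher, CD74 had adjusted p = 0.195 and IGFBP5 adjusted p = 0.274. In those 8 libraries 1584 genes passed, 43 of 52 replication genes and 45 of 66 MYC targets fell, 19 of 37 mesenchymal and 14 of 51 interferon genes rose, and the calls of heat shock (adjusted p = 0.0635) and mitosis (adjusted p = 0.336) ended.

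**Figure D2:**
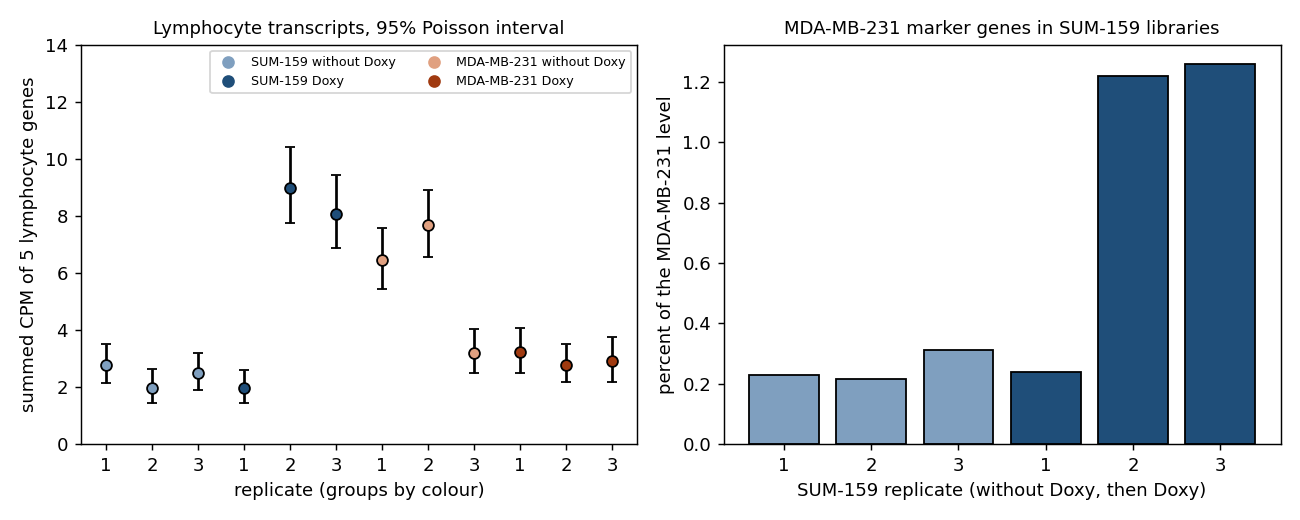
Left, summed CPM of PTPRC, CD3D, CD3E, CD3G and CD2 in each library (y axis, CPM over the library total; points with 95% exact Poisson intervals, colour for group, x axis for replicate). Right, summed level of 29 MDA-MB-231 marker genes in each SUM-159 library as percent of their mean level in MDA-MB-231: SUM-159 Doxy replicates 2 and 3 reach 1.22% and 1.26%, and the other 4 lie between 0.215% and 0.311%.

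In MDA-MB-231, cell cycle genes were higher with Doxy. Of 52 DNA replication and S phase genes, 47 rose and 1 fell (the same when adjusted over the list alone), with a median log2 fold change of 1.01. MCM3 went from 85.0 ± 4.18 to 220 ± 4.86 CPM (SD, n = 3), 2.59-fold higher (adjusted p = 1.96e-09), and MCM4 (2.33-fold) and the ribonucleotide reductase subunit RRM2 (2.92-fold) rose, as did PCNA (2.37-fold), whose reads can be shared with pseudogenes. Of 52 mitotic genes, 46 rose and 1 fell (48 and 2 when adjusted over the list alone), with a median of 0.78. They included the kinesin KIF20A (4.22-fold higher), the proliferation marker MKI67 (2.43-fold) and the spindle factor TPX2 (1.74-fold). Enzymes of lipid synthesis rose as well. Of 25 cholesterol synthesis genes 21 rose and none fell (21 and 1 when adjusted over the list alone), with INSIG1 at 2.71-fold, and of 18 fatty acid synthesis genes 12 rose and 2 fell (13 and 2 when adjusted over the list alone), with the desaturase SCD at 3.25-fold and SREBF1, a regulator of lipid synthesis, at 1.92-fold. Of 25 heat shock proteins 14 rose and none fell (15 and 2 when adjusted over the list alone), among them HSPA8 (1.9-fold) and HSP90AA1 (1.88-fold). Of 77 nuclear-encoded respiratory chain subunits 25 rose and 3 fell (the same when adjusted over the list alone), with NDUFB6 at 1.59-fold. Camera called these 6 lists, at adjusted p = 3.33e-25 for replication, 1.5e-21 for mitosis, 2.77e-09 for cholesterol, 0.000331 for fatty acids, 0.000417 for heat shock and 0.00111 for the respiratory chain. With an estimated correlation heat shock had adjusted p = 0.0672 and the respiratory chain adjusted p = 0.596, and the other 4 were called.

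Stress, inflammatory and amino acid genes were lower with Doxy in MDA-MB-231. Of 36 ATF4 targets, 34 fell and 1 rose (the same when adjusted over the list alone), with a median of -1.46. Asparagine synthetase ASNS went from 340 ± 21.0 to 42.9 ± 2.69 CPM (SD, n = 3), 7.92-fold lower (adjusted p = 5.37e-11), PSAT1 of serine synthesis was 4.18-fold lower and the tRNA synthetases SARS and WARS 3.03-fold and 2.81-fold. Of 34 NF-kB and cytokine genes 29 fell and 2 rose (30 and 2 when adjusted over the list alone), with a median of -1.05: interleukin IL1A (7.65-fold) and the chemokines CCL20 (7.96-fold) and CXCL2 (5.76-fold) fell, and PTGES rose (0.49, SE 0.13). Of 21 serine and one-carbon genes 13 fell and 2 rose (the same when adjusted over the list alone), with MTHFD2 2.69-fold lower. Of 25 glutamine and polyamine genes 12 fell and 3 rose (13 and 3 when adjusted over the list alone), with the glutamine carrier SLC1A5 3.13-fold and ornithine decarboxylase ODC1 2.35-fold lower, while glutamine synthetase GLUL rose (0.26, SE 0.07). Of 26 hypoxia genes 17 fell and 1 rose (18 and 2 when adjusted over the list alone), with ANGPTL4 11.4-fold and VEGFA 1.88-fold lower and CA12 higher (0.55, SE 0.11). Of 24 immediate early genes 16 fell and 2 rose (17 and 2 when adjusted over the list alone), with EGR1 4.13-fold and the phosphatase DUSP1 3.23-fold lower and DUSP4 higher (0.59, SE 0.14). Of 23 endoplasmic reticulum chaperones and stress genes 13 fell and 1 rose (13 and 2 when adjusted over the list alone), with the sensor ERN1 3.17-fold and HSPA5 1.85-fold lower. Camera called these 7 lists, at adjusted p = 7.78e-26 for ATF4, 3.32e-09 for NF-kB, 5e-05 for serine, 0.00041 for glutamine, 2.68e-06 for hypoxia, 2.76e-05 for immediate early genes and 8.09e-05 for the chaperones. With an estimated correlation NF-kB had adjusted p = 0.099 and immediate early genes adjusted p = 0.296, and the other 5 were called.

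Genes of ribosome production went down in MDA-MB-231, and direct MYC targets divided. Of 75 ribosome biogenesis factors 40 fell and 6 rose (41 and 7 when adjusted over the list alone), with RRP12 1.88-fold and DKC1 1.68-fold lower, while IMP3 rose (0.78, SE 0.16). Of 66 MYC targets 36 fell and 14 rose (40 and 15 when adjusted over the list alone), with ODC1 and DKC1 among the lower ones. Of those that rose, MCM5 (3.46-fold) and MCM4 are replication genes, UNG (1.67-fold) is a DNA repair enzyme and PLK1 (1.98-fold) a mitotic kinase. Of 78 cytosolic ribosomal proteins 52 fell and none rose (59 fell when adjusted over the list alone), with a median of -0.31 and RPL10A 1.72-fold lower, and their reads can be shared with processed pseudogenes. The list of CDK inhibitors and genes repressed by MYC had 12 of 24 members lower and 3 higher (13 and 3 when adjusted over the list alone): TXNIP (2.65-fold) and its relative ARRDC4 (4.25-fold), which respond to glucose, fell, as did the stress factor DDIT3 (3.25-fold), while the inhibitor CDKN2C (3.58-fold) and THBS1 (1.5-fold) rose. Of 51 interferon genes 18 rose and 7 fell (19 and 7 when adjusted over the list alone), with TRIM22 higher (1.17, SE 0.21) and IRF7 lower (-0.84, SE 0.19). Camera's adjusted p was 8.11e-07 for ribosome biogenesis, 0.000435 for MYC targets, 2.77e-09 for ribosomal proteins, 0.00713 for the inhibitors and 0.0396 for interferon genes. With an estimated correlation MYC targets had adjusted p = 0.099, ribosomal proteins adjusted p = 0.454 and interferon genes adjusted p = 0.424, and the other 2 were called. The interferon call ended without replicate 3 of the group without Doxy (adjusted p = 0.116) or Doxy replicate 2 (adjusted p = 0.0634).

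Among the largest rises in MDA-MB-231 under the naming rule were those of LGALS12 (6.7-fold), FAM111B (5.69-fold), the integrin ITGB8 (4.64-fold), KIF20A, METTL7A (4.12-fold), PDE4B (3.74-fold) and NEURL1B (3.7-fold). The largest falls were of the matrix protease MMP10, which went from 40.6 ± 3.31 to 1.91 ± 0.189 CPM (SD, n = 3; 21.1-fold), SPX (17.6-fold), the protease PAPPA2 (11.5-fold), ANGPTL4, the epithelial splicing regulator ESRP1 (9.55-fold), ESM1 (8.01-fold), CCL20 and ASNS. In all, 5912 of 15299 genes changed, 2915 higher and 2997 lower, and 886 at least 2-fold, 371 higher and 515 lower. MDA-MB-231 without Doxy replicates 1 and 2 carried lymphocyte transcripts (6.44 and 7.67 CPM) against 2.79 to 3.22 CPM in the other 4 MDA-MB-231 libraries. In the 8 libraries with few of them, which leave 1 MDA-MB-231 library without Doxy, 3922 genes passed, 46 of 52 replication genes rose, and 34 of 36 ATF4 targets, 28 of 36 NF-kB genes and 25 of 78 ribosomal protein genes fell.

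**Figure D3:**
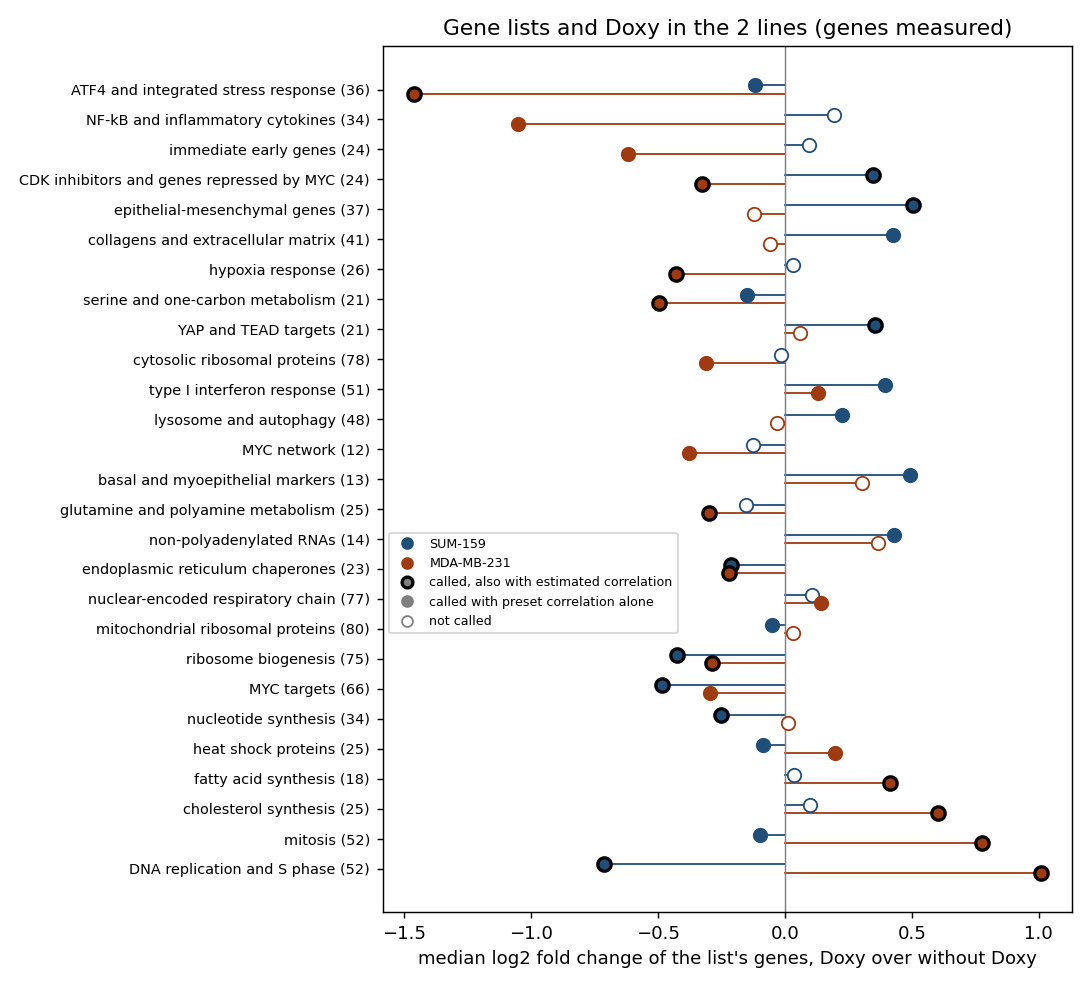
Median log2 fold change with Doxy (x axis) of each list called in either line (y axis, number of genes measured in brackets), SUM-159 in blue and MDA-MB-231 in red. Filled points were called by camera, and black rims mark those also called with an estimated correlation: the replication list lies at -0.71 in SUM-159 and at 1.01 in MDA-MB-231, and the ATF4 list at -0.12 and -1.46.

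Cell cycle and stress genes answered Doxy differently in the 2 lines, by a test of the difference itself (log2 fold change in SUM-159 minus that in MDA-MB-231). MCM4 (-2.27, SE 0.31), MCM3 (-2.22, SE 0.31), PCNA (-1.99, SE 0.28) and TCF19 (-2.16, SE 0.32) were relatively lower in SUM-159, as were the desaturase SCD (-2.11, SE 0.29) and the lamin LMNB1 (-1.67, SE 0.24). On the other side stood ASNS (2.65, SE 0.37), PSAT1 (1.71, SE 0.25), SARS (1.57, SE 0.23), PAPPA2 (3.27, SE 0.47) and IGFBP3 (2.25, SE 0.32). The fall of MYC was larger in MDA-MB-231 (0.81, SE 0.17, adjusted p = 8.4e-05). Among lists, 50 of 52 replication genes and 45 of 52 mitotic genes were relatively lower in SUM-159 (50 and 48 when adjusted over the list alone). The relatively higher ones were 32 of 36 ATF4 targets, 26 of 34 NF-kB genes, 24 of 37 mesenchymal genes and 19 of 26 hypoxia genes (33, 29, 24 and 19 when adjusted over the list alone). These 6 lists were called at adjusted p = 8.1e-47, 1.92e-25, 5.27e-23, 3.28e-09, 6.62e-06 and 7.45e-06 in that order, and NF-kB had adjusted p = 0.0782 with an estimated correlation. Over all genes 4162 differed, 2500 relatively higher and 1662 relatively lower in SUM-159, and with library totals as the scaling the split was 2080 against 1999. In the 8 libraries with few lymphocyte transcripts 1790 genes differed and with a term for the other 4 libraries 1524, against 6391 with the trend on GC content removed. The NF-kB list went from a median difference of 1.60 to 0.53 in the 8 libraries, with 11 of 36 members relatively higher.

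**Figure D4:**
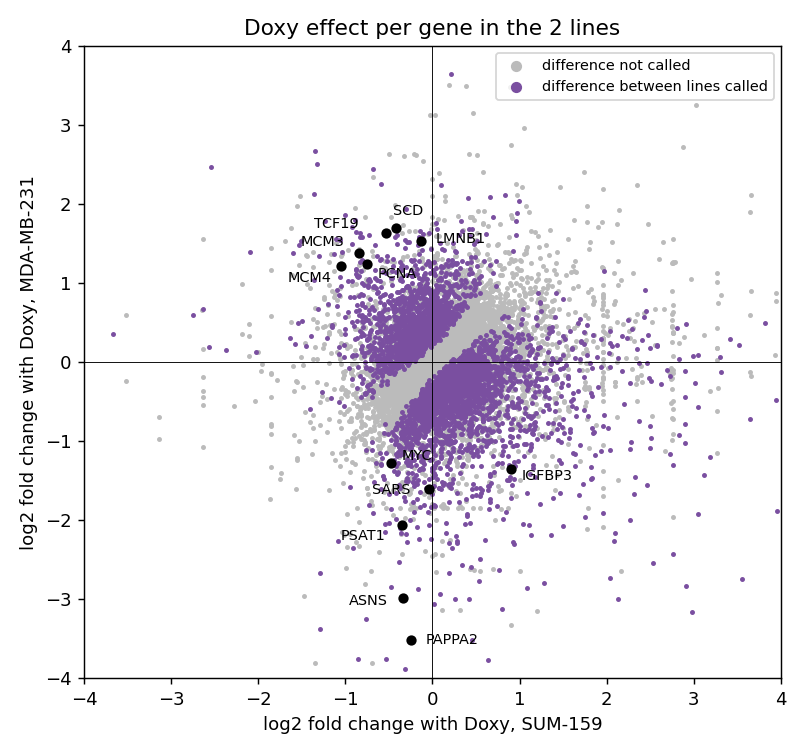
Log2 fold change with Doxy of each gene in SUM-159 (x axis) and MDA-MB-231 (y axis), 15243 genes within the axes and 56 outside them. Purple points differed between the lines at adjusted p under 0.05 by edgeR, and the named black points are MYC and genes among those with the lowest p of the difference in each direction: MCM3, MCM4, PCNA and TCF19 lie upper left, ASNS and PAPPA2 at the bottom.

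Part of the response ran the same way in both lines. RRP12, DKC1, MTHFD1L (1.61-fold in SUM-159 and 2.16-fold in MDA-MB-231), PSAT1 and HSPA5 fell in both, and CDKN2C, THBS1 and KIF20A rose in both. The lists called lower in both lines were MYC targets, ribosome biogenesis, serine and one-carbon metabolism, ATF4 targets and endoplasmic reticulum chaperones, and the list called higher in both was the interferon response. With an estimated correlation only ribosome biogenesis and the chaperones were called in both. MYC targets had adjusted p = 0.099 in MDA-MB-231, and serine metabolism 0.0542 and ATF4 targets 0.316 in SUM-159, and interferon genes had 0.0937 in SUM-159 and 0.424 in MDA-MB-231. In both lines 813 genes rose and 618 fell, 1431 in the same direction, against 475.6 and 315.2 for independent lists of those sizes, and another 713 were called in opposite directions, against 795.5. Across all genes, which are not independent replicates, the log2 fold changes of the lines had a Pearson r of 0.0259 and a Spearman rho of 0.118. The 1431 became 553 in the 8 libraries with few lymphocyte transcripts, 708 with a term for the other 4 libraries and 2507 with the trend on GC content removed.

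Without Doxy, the lines differed in cell type markers and signalling genes, and since they were grown in different media, that of SUM-159 with insulin and hydrocortisone, line and medium cannot be told apart. SUM-159 had more RNA of the basal and fibroblast markers MME (404 ± 37.4 against 2.44 ± 0.393 CPM), PDPN (221 ± 0.963 against 1.61 ± 0.707 CPM), COL1A1 (561 ± 64.9 against 16.1 ± 2.1 CPM) and TP63 (21.2 ± 1.73 against 0.469 ± 0.264 CPM), of the pentraxin NPTX2 (141 ± 9.27 against 0.491 ± 0.128 CPM) and of MYC itself (log2 difference 1.31, SE 0.20). Of 13 basal markers 8 were higher and 4 lower in SUM-159, with no call (adjusted p = 0.333). The lower ones were EGFR, LAMA3, SFN and MYLK. Of 10 fibroblast markers 7 were higher and 2, COL1A2 (-2.63, SE 0.53) and LUM (-2.75, SE 0.98), lower. Camera's adjusted p for that list was 0.0328, and 0.28 with an estimated correlation. Without replicate 1 of SUM-159 without Doxy the value of LUM was -6.25, so its size depends on that library. MDA-MB-231 had more of the epithelial markers KRT19 (256 ± 34.4 against 0.477 ± 0.138 CPM), CLDN7 (147 ± 21.4 against 0.159 ± 0.0852 CPM) and SPDEF (40.2 ± 4.88 against 0.0746 ± 0.0563 CPM), and of the cytokine CSF2 (257 ± 23.9 against 0.118 ± 0.0588 CPM; SD, n = 3 throughout). Of 16 luminal epithelial markers 11 were lower and 3 higher in SUM-159 (adjusted p = 0.0256, and adjusted p = 0.35 with an estimated correlation). IGFBP1, CALB2, AGR2 and TMPRSS2 had no count in the 3 SUM-159 libraries without Doxy and were at least 294-fold, 104-fold, 85.7-fold and 77.3-fold higher in MDA-MB-231, each against a floor of 3 counts per library. All 78 measured cytosolic ribosomal protein genes were higher in SUM-159 (median 1.07), as were 48 of 66 MYC targets, with 8 lower (78, 49 and 8 when adjusted over the list alone). Lower in SUM-159 were 30 of 34 NF-kB and cytokine genes, 37 of 51 interferon genes and 21 of 26 hypoxia genes, with 4, 11 and 4 higher (the same when adjusted over the list alone). These 5 lists were called at adjusted p = 1.73e-15, 4.64e-05, 8.77e-07, 0.00234 and 0.0016, and had adjusted p = 0.35, 0.103, 0.257, 0.28 and 0.103 with an estimated correlation. In all, 11802 genes differed, 5743 higher in SUM-159 and 6059 higher in MDA-MB-231, and 5722 by at least 2-fold. With library totals as the scaling the median of all genes moved from -0.02 to -0.12 on the log2 scale.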

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

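The effect of Doxy differed between SUM-159 and MDA-MB-231 by a direct test, and the values of this part are differences of log2 fold changes, SUM-159 minus MDA-MB-231. The tests on library batches, on a stress response and on culture state and the counts of other splits were chosen after the results were seen. Over all genes 4162 differed. Single genes among those with the lowest p were ASNS at 2.65, PAPPA2 at 3.27, IGFBP3 at 2.25, SARS at 1.57 and PSAT1 at 1.71 on the side of SUM-159, and MCM4 at -2.27, MCM3 at -2.22, SCD at -2.11, PCNA at -1.99, LMNB1 at -1.67 and TCF19 at -2.16 on the side of MDA-MB-231. MYC itself differed by 0.81, its fall being the larger in MDA-MB-231.

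Of 35 lists 22 differed, and 15 of these also with an estimated correlation. Relatively lower in SUM-159 were 9 lists, with median differences of -1.66 for DNA replication, -0.83 for mitosis, -0.29 for nucleotide synthesis, -0.22 for MYC targets, -0.14 for ribosome biogenesis, -0.41 for cholesterol synthesis, -0.33 for fatty acid synthesis, -0.32 for heat shock proteins and -0.0537 for the respiratory chain. Relatively higher in SUM-159 were 13 lists, with 1.60 for NF-kB and cytokines, 1.38 for ATF4 targets, 0.79 for immediate early genes, 0.69 for CDK inhibitors and genes repressed by MYC, 0.60 for mesenchymal genes, 0.59 for hypoxia, 0.53 for serine metabolism, 0.50 for collagens and matrix, 0.37 for YAP and TEAD targets, 0.35 for lysosome and autophagy, 0.30 for cytosolic ribosomal proteins, 0.24 for glutamine metabolism and 0.19 for p53 targets. The lists lost with an estimated correlation were MYC targets (adjusted p = 0.0524), ribosomal proteins (0.573), the respiratory chain (0.639), NF-kB (0.0782), matrix (0.0714), lysosome (0.223) and immediate early genes (0.223). The call of the respiratory chain ended without replicate 2 of SUM-159 without Doxy (adjusted p = 0.0618), without SUM-159 Doxy replicate 1 (0.0744) and without replicate 2 of MDA-MB-231 without Doxy (0.0948). With fry the respiratory chain (adjusted p = 0.288) and the cytosolic ribosomal proteins (0.0526) were not called. The call of the cytosolic ribosomal proteins also ended with a term for the 4 libraries with more lymphocyte transcripts (adjusted p = 0.0854).

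Of 100 splits of the libraries within each line, the real one included, 1 gave as many genes that differ (4162, against 2047 for the highest other split). The other splits with the highest counts, 2047 and 1944, kept the real MDA-MB-231 groups and mixed those of SUM-159. Every other split drawn mixed the groups of at least 1 line, which takes most of the calls of that line away, so chance is not taken as excluded for the count of genes that differ. For lists, 1 of 100 gave as many (22 against 21), but the margin is 1 list and the real count was 21 without replicate 2 of SUM-159 without Doxy, so chance is not taken as excluded for the lists. For genes called the same way in both lines, 1 of 100 gave as many (1431 against 0). The mixed splits call 0 to 2 genes within a line, so that count holds nothing on chance in the overlap.

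The replication list fell in SUM-159 (50 of 52) and rose in MDA-MB-231 (47 of 52). A difference between the 8 libraries with few lymphocyte transcripts and the other 4 is argued against as the cause. The median difference was -1.66 in the 8, which leave 1 SUM-159 Doxy library and 1 MDA-MB-231 library without Doxy. It was -1.63 with a term for the other 4 libraries (camera's adjusted p = 9.08e-55). The labels give no batch, and a batch that runs with the Doxy groups could not be tested. A mitochondrial stress response to doxycycline would raise ATF4 targets, and their medians of -1.46 in MDA-MB-231 and -0.12 in SUM-159 show no net rise. Every Doxy library also had less MYC, and no library without the construct was analysed. The medians therefore cannot separate an effect of Doxy itself from that of MYC, and this explanation stays open. The culture state of the MDA-MB-231 libraries without Doxy stays open: hypoxia genes were lower with Doxy there (median -0.43), and the labels give no density or harvest time to set against it. A different response of the lines to less MYC also stays open as a biological hypothesis, untested here, and with it the media, which differ between the lines.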

How the results depend on the processing

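The alternatives on lymphocyte transcripts, on genes higher in MDA-MB-231, on subtraction and on GC content were chosen after the data were examined, the others before. No direction reversed for MYC, 515 further results for named genes and 59 for lists in the alternatives run on each. Not run on every gene result were the block (334 of the 515), the libraries of 1 line (223, and 37 of the 59 lists), the removal of genes higher in MDA-MB-231 (444), the stricter filter (509) and the 8 libraries (514). MYC passed in both lines in all of them. With 1 library left out, its log2 fold change ran from -0.52 to -0.44 in SUM-159 and from -1.37 to -1.25 in MDA-MB-231. The counts ran from 2658 to 4675 genes in SUM-159 (2719 without replicate 1 of the group without Doxy, 2658 without Doxy replicate 2 and 2691 without Doxy replicate 3, all moved by more than 1.5 times), from 4774 to 6131 in MDA-MB-231, from 3141 to 4750 for the difference, from 11251 to 11984 between the lines and from 990 to 1556 for genes called in both lines. Lists called ran from 17 to 23 in SUM-159, from 18 to 20 in MDA-MB-231 and from 21 to 23 for the difference.

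With an estimated correlation 8 lists were called in SUM-159 in place of 18 and 11 in MDA-MB-231 in place of 19. In the 8 libraries with few lymphocyte transcripts 1584 genes passed in SUM-159, 3922 in MDA-MB-231, 1790 for the difference and 553 in both lines. That setting leaves 1 SUM-159 Doxy library and 1 MDA-MB-231 library without Doxy, each assumed to vary like the other groups, and fewer libraries lower such counts by themselves. With a term for the other 4 libraries 2099 genes passed in SUM-159, 1524 for the difference and 708 in both lines. With the trend on GC content removed 6391 genes passed for the difference and 2507 in both lines, and the cause was not tested. With DESeq2, limma-voom, the other scalings, the other filters, counts not rounded, the libraries of 1 line alone, the genes higher in MDA-MB-231 removed or their signal subtracted, each count of genes stayed within 1.5 times the one reported. The share of higher calls in SUM-159, 60.8%, became 49.4% with its 6 libraries alone, 49.6% to 50.4% when any MDA-MB-231 library was left out and 50.2% with the GC trend removed, so which direction had more calls is open, and the cause was not tested.

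Replicates share numbers in the labels. The correlations of the deviations of samples with the same number were 0.021, 0.055 and -0.085 in SUM-159 and 0.16, 0.24 and 0.018 in MDA-MB-231. In SUM-159 2 of 6 samples and in MDA-MB-231 4 of 6 correlated best with their own number, a hint of pairing in MDA-MB-231 that its replicate 3 does not share, so the numbers were not taken to pair the samples. With the replicate block more genes passed, 5194 in SUM-159 against 4105 without it and 6847 in MDA-MB-231 against 5912. For the difference it was 5203 against 4162, and in both lines 1940 against 1431. A pairing by number is therefore not excluded. Heat shock in SUM-159 and the MYC network in MDA-MB-231 lost their calls with the block. No other list and 2 of 334 named results lost theirs with the block.

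Of the 515 gene results, those no longer past the threshold were 73 of 514 in the 8 libraries, 59 with the term, 43 when the least favourable library was left out, 8 with library totals, 6 without a filter, 6 of 223 with the libraries of 1 line, 4 with limma-voom, 3 of 444 without the genes higher in MDA-MB-231, 2 with DESeq2 and 1 each with relative log expression, upper-quartile scaling and GC trend removal. Of the 59 list results, those lost were 25 with an estimated correlation, 7 when the least favourable library was left out, 4 each with fry and without the genes higher in MDA-MB-231, 3 with GC trend removal and 2 each in the 8 libraries, with the term and with the block. In the simulation 8.0% of the smallest planted changes were recovered for the difference of the effects and 16.0% in MDA-MB-231. The simulation gave 115 and 150 calls in these comparisons, against 4162 and 5912 in the data. With more calls a larger unadjusted p passes the Benjamini-Hochberg threshold, so these shares cannot be carried over to the data. The share of small changes missed in the data is therefore not known.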

Other observations

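The tests in this part were chosen after the results were seen, except the test on transcript length and GC content and the test on genes at least 8 times higher in MDA-MB-231, whose outcomes were written down first. Gene lists of this part were also written after the data were examined. Host genes of small nucleolar RNAs, whose spliced RNAs are degraded when translation is active, fell in both lines: 9 of 13 in SUM-159 (median -0.27) and 12 of 13 in MDA-MB-231 (median -0.85), and none rose. GAS5 changed by -0.42 (SE 0.10) and -1.99 (SE 0.27) and ZFAS1 by -0.55 (SE 0.12) and -2.04 (SE 0.28) on the log2 scale, and the effect differed between the lines for 9 of the 13. Cytosolic aminoacyl-tRNA synthetases, which load tRNAs with amino acids, fell in 16 of 20 cases in MDA-MB-231 and rose in 3 (median -0.77), with AARS at -1.48 (SE 0.21) and YARS at -1.35 (SE 0.19), while QARS rose (0.55, SE 0.11). In SUM-159 5 fell and 1 rose, with FARSB lower (-0.76, SE 0.15). Some synthetases, SARS and WARS among them, are also in the fixed list of ATF4 targets.

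Some targets of the glucocorticoid receptor changed in each line, and the list was not tested as a whole. In SUM-159, whose medium held hydrocortisone, 6 of 11 rose and none fell, with CRISPLD2 (0.90, SE 0.16) and SGK1 (0.70, SE 0.17) higher. In MDA-MB-231 5 fell and none rose, with ERRFI1 (-1.17, SE 0.17) and DUSP1 (-1.69, SE 0.26) lower. The effect differed between the lines for 8 of the 11, all relatively higher in SUM-159, and DUSP1 is also an immediate early gene of a fixed list.

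Of 29 MDA-MB-231 marker genes, 28 were higher in SUM-159 Doxy replicates 2 and 3 than in every other SUM-159 library, which is consistent with RNA or reads of MDA-MB-231 in these libraries. In those 2 replicates the excess of the markers had a median of 0.899% of the MDA-MB-231 level, with quartiles of 0.768% and 1.09%. Across markers it rose with that level (Spearman rho 0.689), as RNA or reads of MDA-MB-231 would give. An exchange both ways with MDA-MB-231 without Doxy replicates 1 and 2 is argued against. The excess of SUM-159 markers there was 0.0327 percentage points, against 0.992 the other way. A response of the SUM-159 cells to Doxy stays open, since the median excess of -0.00335% of the MDA-MB-231 level in Doxy replicate 1 is from 1 library. Of 1300 genes at least 8 times higher in MDA-MB-231, 314 were called up in SUM-159 Doxy (24.2%, against 15.6% of the other 13999 genes), of which 212 passed after the subtraction and 70 in the 8 libraries. For 253 of the 314 (80.6%, chance 25%) Doxy replicate 1 lay above all 3 libraries without Doxy. Both explanations stay open for them as well, because it is 1 library and the genes were called partly on it. The 1300 genes were also chosen partly by a low level in SUM-159 without Doxy, the baseline of that effect. A gene low there by chance is tilted toward a higher call, so the 24.2% and the 80.6% can be partly built in. Lymphocyte transcripts, taken from the fixed list of leukocyte markers, were higher in the same 2 libraries (PTPRC at 4.68 and 4.32 CPM against at most 1.58 CPM in the other SUM-159 libraries), and their source was not tested.

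In MDA-MB-231 52 of 78 cytosolic ribosomal proteins fell, with a median of -0.31 and no call of the list with an estimated correlation (adjusted p = 0.454). Transcript length and GC content were examined with 10000 random lists matched on level, length and GC. Their medians centred on -0.0165 (central range -0.14 to 0.0872), and the list's median had percentile 0. Their genes were drawn independently, while ribosomal protein genes vary together (estimated correlation 0.626). That range is therefore too narrow for such a list, and the percentile is no p-value. The matched genes had a median level of 8.66 against 9.61 log2 CPM, so level was matched in part. How closely length and GC were matched was not measured, so these random lists do not decide whether transcript length and GC content are the cause. A difference between the 8 libraries with few lymphocyte transcripts and the other 4 is argued against as the whole cause. The median was -0.22 in the 8 libraries and -0.23 with a term for the other 4. A batch that runs with the Doxy groups could not be tested. The 18 other mRNAs of the terminal oligopyrimidine class had a median of -0.21, with 8 lower and 2 higher, against 1 lower and 2 higher in SUM-159, which is consistent with a response of that class, a hypothesis found and tested on the same data. Reads shared with processed pseudogenes were not tested.

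With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In each of these comparisons 1 of the 10 splits, the real one, gave a result as large: 4105 genes in SUM-159 against 2 in the highest other split, 5912 in MDA-MB-231 against 0 and 11802 between the lines against 0. For lists the values were 18 against 15 in SUM-159 and 19 against 15 in MDA-MB-231, and the other splits called a median of 13 and 12 lists, 13 for the difference. Each other split of a line puts 2 libraries of a group and 1 of the other on either side, so part of the Doxy effect remains in it.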
